A study of Mus musculus with 6 samples.

How the data were processed

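CUT&Tag libraries were made from OG2X129 mouse embryonic fibroblasts, per the labels, with an H3K27ac antibody after CD treatment (2 samples) and after DMSO treatment (2 samples), and with a Flag antibody after overexpression of Flag-tagged Rxra (2 samples). CUT&Tag directs a transposase to the place an antibody binds, so that the released fragments mark that place. The labels do not say whether the Flag-Rxra cells received CD or DMSO, nor at which day of reprogramming any sample was taken. They also do not say whether replicates came from separate cultures.

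The deposited files used here were 4 peak lists. Per the labels, both replicates of an H3K27ac condition name 1 common list, and how the replicates were combined is not given in the sources used here. Each Flag-Rxra replicate had its own list. The submitters' processing notes name fastp 0.20.1, Bowtie2 2.2.5, MACS2 2.1.2, deepTools 3.4.3 and the genome build mm10. Whether a control library entered peak calling is not given in the sources used here, and no control list was used here. The fold enrichment of each peak is a ratio over the background estimated by the authors' peak caller, as deposited. The −log10 q of each peak is also the authors' deposited value. The H3K27ac lists stopped at a −log10 q of 1.00 and the Flag-Rxra lists at 5.00, so H3K27ac regions were called far more leniently than Flag-Rxra peaks. The H3K27ac lists are of the broad-region type and the Flag-Rxra lists of the narrow-peak type. Fold and −log10 q are therefore not on a common scale between them. Fold and −log10 q were used to describe, rank or filter peaks within a list. Fold was also correlated between the Flag-Rxra replicates, and it weighted covered bases in an alternative. Where an alternative or a figure needed the strongest peaks, these were ordered by −log10 q and then by fold, a choice made after the data were seen. The lists hold no read counts, so the sequencing depth is unknown, and a difference in depth between the H3K27ac lists cannot be excluded. The peak names inside the Flag-Rxra lists carry other codes than the sample titles, and the assignment of lists to replicates follows the labels. Signal tracks named in the labels were not analysed here.

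All computations were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Peaks on chromosomes 1 to 19, X and Y were analysed, and those on the mitochondrial genome and on unplaced contigs were only counted. Gene positions came from a RefSeq table of GRCm38.p6, the same assembly as mm10, with 21887 protein-coding genes on these chromosomes. That table gives the start and end of each gene but no strand, transcript or exon. The design fixed before the data were examined had called for transcription start sites. In their place, windows of 1 kb around both annotated ends of a gene were used, so these windows include 3′ ends and miss internal starts. Peaks were therefore divided into those near a gene end, those inside a gene and those outside genes, with no exon or intron class. A planned motif search was not run because it needs a genome sequence, which was not used here, and the VL30 repeats named in the series title were not located for the same reason.

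Overlap meant 1 bp or more. Shared Flag-Rxra peaks were replicate 1 peaks that overlapped a replicate 2 peak, and their coordinates are those of replicate 1. A gene counted as bound when a shared peak overlapped the 1 kb window of either end, and as marked when an H3K27ac region did. Bound therefore means a called peak, which without a control library does not establish that Rxra binds there. The location of a peak was taken from its summit. Chance overlap was the mean of 100 random placements of a list with the same widths on the same chromosomes, between the outermost features seen on each chromosome. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only, since neighbouring regions and genes are not independent replicates. Bootstrap intervals of CD to DMSO ratios resampled peaks or genes 1000 times and have the same limit.

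Gene lists were fixed before the data were examined: 14 for pathways or cell states and 5 for markers of other cell types. Each was tested with a two-sided Fisher's exact test of bound members against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 19 lists and a threshold of 0.05. These p-values describe the peak lists, not variation between cultures. H3K27ac levels were compared between conditions without a test, because each condition had 1 list. The share of CD-only and of DMSO-only regions that held a shared Flag-Rxra peak was compared with a two-sided Fisher's exact test, which compares those lists and not the conditions. For each gene, the bases covered by H3K27ac regions were summed within 2.5 kb of its ends (near) and from there out to 50 kb (far). The median CD minus DMSO difference of a gene list was then given as its percentile among 10000 random lists of the same size, matched on deciles of the mean covered bases. A median outside the percentiles 2.5 to 97.5 was counted as standing apart, a bound chosen after the data were seen.

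Named genes followed a rule fixed before the data were examined. For Flag-Rxra these were the 12 genes with the best worse rank of fold over both replicates near a gene end, the 8 best such peaks away from gene ends with the nearest gene, all bound members of the RNA exosome list and up to 4 best-ranked bound members of the other lists. For H3K27ac they were the 12 genes with the largest CD minus DMSO difference in bases covered within 50 kb in each direction, among those whose sign stayed with covered lengths matched, and up to 4 members of each list with the largest differences. The text names a part of the genes that the rule for list members takes.

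The steps were tested on simulated data. With 60.1% of replicate 1 peaks given a partner, an overlap of 60.2% was recovered. In 400 simulated lists of 16 genes with 75% bound, the Fisher test over all 21887 genes called 79.5%, and it called 0.933% of 1500 unchanged lists. For the H3K27ac percentiles, also over 21887 genes, 1000 added bases put 60% of 10 lists of 20 genes outside the bounds, against 2.5% of 40 unchanged lists. The simulated lists held random genes, and for the Fisher test binding was drawn independently for each gene. These rates of false calls therefore do not carry over to lists of genes related in function or activity. Alternatives fixed beforehand were a reciprocal overlap of 50%, a −log10 q of 5, lists matched in number or covered length, a 3 kb window, a background of marked genes, summits in place of peaks, bases weighted by fold, and each Flag-Rxra replicate alone. Others were added after the data were seen. They were a −log10 q of 20 for Flag-Rxra and of 2 for H3K27ac, leaving out peaks in the strongest H3K27ac regions of both lists, 1 member per locus, and peaks moved by 50000 to 500000 bp as another chance level.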

Results

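The series profiled chromatin in OG2X129 mouse embryonic fibroblasts undergoing chemical reprogramming, in which small molecules turn somatic cells into pluripotent stem cells. Its title names CD3254, a synthetic agonist of the retinoid X receptor (RXR), RXRα, the RNA exosome, the retroelement MMVL30 and inflammation. H3K27ac, a histone mark of active promoters and enhancers, was mapped by CUT&Tag after CD and after DMSO treatment, and Flag-tagged Rxra was mapped in cells that overexpressed it. The 6 samples formed 3 groups of 2. On chromosomes 1 to 19, X and Y, the CD list held 104437 H3K27ac regions covering 37.3 Mb, with a median width of 270 bp, and the DMSO list held 75482 regions covering 31.1 Mb, with a median width of 317 bp. The Flag-Rxra lists held 28243 peaks in replicate 1 and 45999 peaks in replicate 2, with median fold enrichments of 9.03 and 10.8 over the authors' background. H3K27ac regions had median folds of 3.14 in CD and 3.11 in DMSO, and only 681 CD and 721 DMSO regions reached a −log10 q of 5. Their lists are of the broad-region type and the Flag-Rxra lists of the narrow-peak type, so these folds are not directly comparable. Each H3K27ac condition had 1 list for both replicates, so its values have no replicate error.

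The first comparison asked where Flag-Rxra peaks lay. Among protein-coding genes, the Flag-Rxra peak near a gene end with the best rank of fold over both replicates had its summit 904 bp from an end of Wls, a gene needed for Wnt secretion. This peak (chromosome 3, 159939405 to 159939742) had a fold of 47.2 in replicate 1 and 68.9 in replicate 2. The other genes among the 12 with the best ranks were Kbtbd7, Mfap2, Nkapl, Tent2, Cdc6, Txlng, Polr3k, Eloa, Ccser2, Zmat2 and Lars2. Cdc6 acts in the licensing of replication origins, Polr3k encodes a subunit of RNA polymerase III, and Lars2 encodes the mitochondrial leucyl-tRNA synthetase. Over the 12 genes the fold ran from 22.9 to 47.2 in replicate 1 and from 33.8 to 68.9 in replicate 2. The Cdc6 peak (chromosome 11, 98907620 to 98908104) had folds of 24.4 and 39.3 with its summit 27 bp from the gene's end. The Kbtbd7 peak (chromosome 14, 79426350 to 79426790) had folds of 31.5 and 53.0. Of the 12 peaks, 6 overlapped a CD and 8 a DMSO H3K27ac region. The peaks at Wls, Mfap2, Polr3k and Lars2 lay in H3K27ac regions far stronger than is usual in those lists. At Wls these regions had −log10 q of 2882 in CD and 1430 in DMSO. Reads that pile up at the same places with any antibody could also give such peaks. Without a control library it stays open whether the peaks at Wls, Mfap2, Polr3k and Lars2 mark Rxra binding.

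Away from gene ends, the 8 strongest shared peaks had folds of 54.0 to 57.6 in replicate 1 and 79.9 to 86.8 in replicate 2. They lay inside Flt1 (chromosome 5, 147611435 to 147611706), Lama1 (chromosome 17, 67741362 to 67741635), Ttc21b (chromosome 2, 66189206 to 66189518) and Chl1 (chromosome 6, 103649058 to 103649295), and outside genes nearest to Adgre5, Creb3l1, Ajap1 and Gm3376. All 8 lay in very strong H3K27ac regions of both lists, with −log10 q of at least 444 in CD and at least 283 in DMSO. At Chl1 these values were 9158 in CD and 8270 in DMSO. The 8 peaks may therefore be places where reads pile up with any antibody, and no control library was used here to tell. They are not secure Rxra sites, nor secure sites of H3K27ac. The peak nearest to Adgre5 (chromosome 8, 83756723 to 83757087), 15606 bp from the gene, ranked first in both replicates.

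Flag-Rxra peaks were concentrated at gene ends. No control library was used here, so it stays open how many of these peaks mark Rxra rather than signal that any antibody would give. Of 17623 shared peaks, 35.1% (95% interval 34.4 to 35.8) had their summit within 1 kb of a gene end, 34.1% inside a gene farther from its ends and 30.7% outside genes. Random placement put 3.19% near gene ends, and peaks moved by 50 to 500 kb gave 5.47%. In replicate 1, 17623 of 28243 peaks (62.4%, 61.8 to 63.0) overlapped a replicate 2 peak, against 1.14% by random placement. In replicate 2, 40.5% (40.1 to 41.0) overlapped a replicate 1 peak. Fold enrichments of the 18671 overlapping pairs had a Spearman correlation of 0.548 across peaks, which are not independent replicates. Replicate 2 alone put only 20.5% of its peaks near gene ends, and replicate 1 alone 29.8%. With an overlap of 50% of both peaks, 39.97% of replicate 1 peaks were shared.

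**Figure D1:**
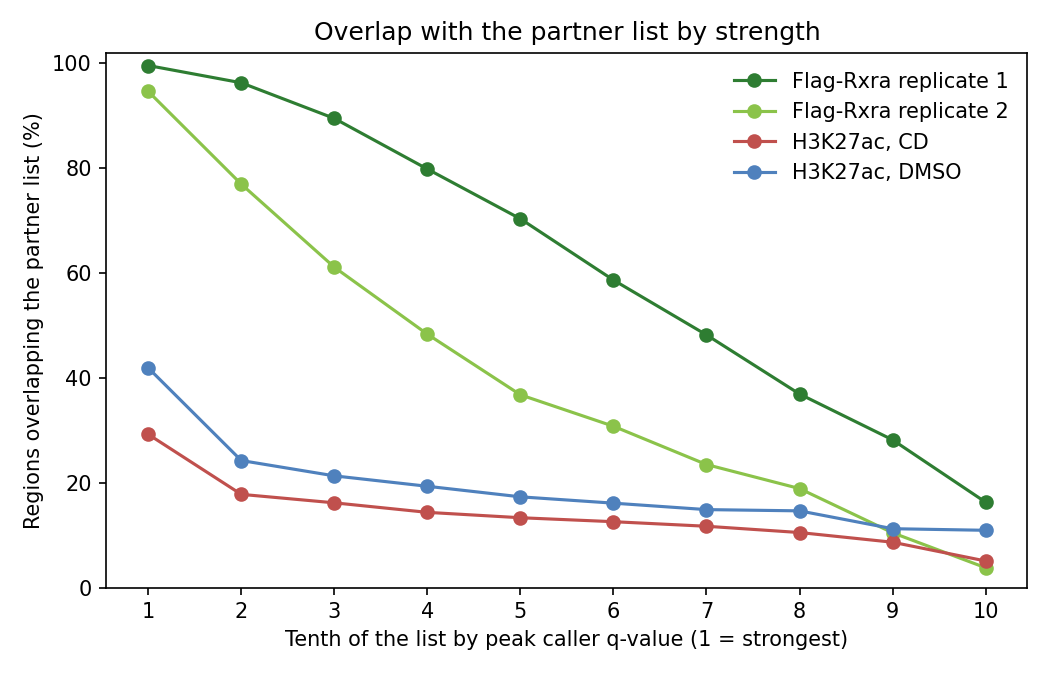
Percent of regions that overlap the partner list (the other Flag-Rxra replicate, or the other H3K27ac condition) on the y axis, for each 10% of a list ordered by peak caller q-value on the x axis, 1 line per list. The strongest 10% of Flag-Rxra replicate 1 overlapped replicate 2 in 99.6% of peaks and the weakest in 16.3%, while the strongest 10% of H3K27ac regions overlapped the other condition in 29.2% for CD and 41.9% for DMSO.

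Genes of the RNA exosome, the complex that degrades and trims RNA from its 3′ end, had a Flag-Rxra peak near an end more often than other genes. Flag-Rxra peaks lay at 10 of 14 members (71.4%, 41.9 to 91.6), against 32.5% of the other protein-coding genes (two-sided Fisher's exact test, adjusted p = 0.0158). The bound members were Exosc1, Exosc2, Exosc4, Exosc5, Exosc7, Exosc8, Exosc9, Exosc10, Dis3l and Mphosph6, and those without a shared peak were Exosc3, Exosc6, Dis3 and C1d. The best-ranked peak lay at Exosc5 (chromosome 7, 25658704 to 25659241), with folds of 16.3 and 30.4 and its summit 45 bp from the gene's end. This peak spans the gap between Exosc5 and its neighbour Bckdha and reaches the annotated ends of both. Exosc1 had folds of 13.8 and 31.3 and Mphosph6 12.8 and 25.4. The weakest of the 10 by rank lay at Dis3l, a cytoplasmic exosome nuclease, with folds of 7.82 and 8.05. An H3K27ac region lay at the ends of all 10 bound members in DMSO and of 7 in CD, all but Exosc2, Exosc4 and Exosc8. The DMSO regions at the peaks of Exosc2, Exosc4 and Exosc8 had −log10 q of only 1.29, 1.55 and 2.02, where the list stops at 1.00. With regions of 2 or more, 5 of the 14 members had more covered bases within 2.5 kb in CD, 6 had more in DMSO and 3 were equal. The exosome call was lost against genes with an H3K27ac region only, where 10 of 13 members and 50.6% of other genes were bound (Fisher's exact test, adjusted p = 0.251), and with Flag-Rxra peaks of −log10 q of 20 or more (6 of 14, adjusted p = 0.344 by Fisher's exact test). Over the 6 other alternatives its adjusted p by Fisher's exact test ran from 0.000924 to 0.0173. Of these, a −log10 q of 5 and 1 member per locus left its peaks and members unchanged, so they could not alter the call. Exosome cofactors, bound at 7 of 11 genes, among them Zcchc7 and Mtrex, the nuclear exosome helicase, did not pass (Fisher's exact test, adjusted p = 0.149).

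**Figure D2:**
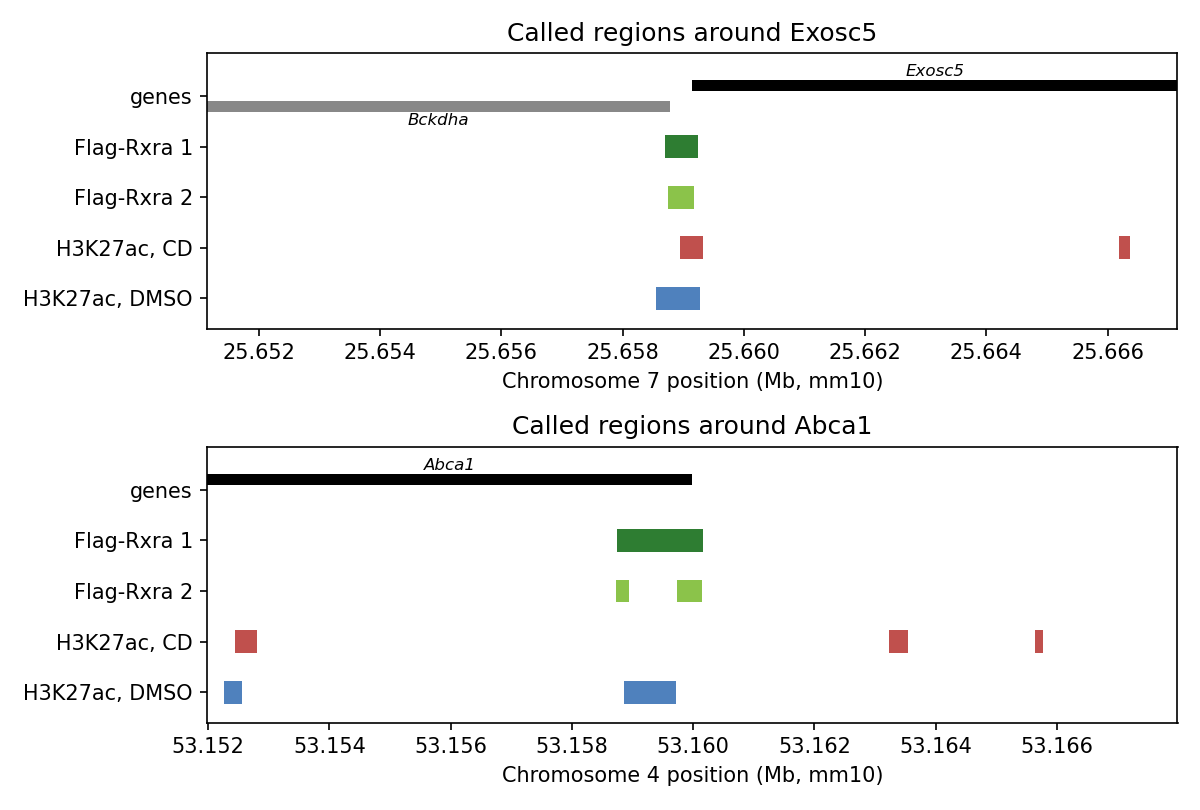
Positions of called regions (x axis, Mb of mm10) in each of the 4 lists (rows) with protein-coding genes above, in 16 kb windows centred on one end of Exosc5 and of Abca1. At Exosc5 all 4 lists have a region at the gene's end, and at Abca1 both Flag-Rxra lists and the DMSO list have one and the CD list has none there. The DMSO region at the Abca1 peak has a −log10 q of only 1.43, where the list stops at 1.00.

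The highest shares were found for cholesterol synthesis genes, bound at 14 of 16 (87.5%, 61.7 to 98.4, adjusted p = 0.000127 by Fisher's exact test), and for AP-1 and other somatic transcription factors, bound at 15 of 18 (83.3%, 58.6 to 96.4, adjusted p = 0.000127 by Fisher's exact test). Dhcr7 (folds of 17.2 and 23.7) and Hmgcs1 (16.6 and 23.6), enzymes of sterol synthesis, led the former list, and Fosl2 (12.1 and 17.0) and Atf3 (11.6 and 15.9) the latter. Runx1, Runx2 and Cebpd had no shared peak. RXR heterodimer targets were bound at 16 of 25 genes (64.0%, adjusted p = 0.0122 by Fisher's exact test), among them Lpcat3 (folds of 18.4 and 25.1), Pdk4 (16.3 and 18.3) and Abca1, a cholesterol exporter (11.6 and 17.9). Housekeeping genes also passed, at 10 of 15 (66.7%, adjusted p = 0.0371 by Fisher's exact test). The cholesterol and AP-1 calls stayed against marked genes only (13 of 13 and 13 of 15, adjusted p = 0.00467 and 0.0470 by Fisher's exact test). The RXR target and housekeeping calls were lost there (adjusted p = 0.331 and 0.147 by Fisher's exact test), and also without replicate 1 (0.244) and without replicate 2 (0.155), respectively. Both were lost with Flag-Rxra peaks of −log10 q of 20 or more (12 of 25, adjusted p = 0.0576, and 6 of 15, adjusted p = 0.344, by Fisher's exact test). There 48% and 40% of the lists were bound, against 24.2% of other genes. The housekeeping call was also lost without peaks in the strongest H3K27ac regions of both lists (9 of 15, adjusted p = 0.110 by Fisher's exact test).

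No other list passed with both replicates. Without replicate 1, exosome cofactors (9 of 11), nuclear receptors and coregulators (17 of 25) and retroelement silencing genes (13 of 18) passed as well (adjusted p = 0.0397 each by Fisher's exact test), and without replicate 2 so did fibroblast and mesenchymal genes (18 of 24, adjusted p = 0.00637 by Fisher's exact test). Among genes of interest to the title, 9 of 25 interferon and nucleic acid sensing genes were bound, led by Irf9 (18.2 and 25.4), and 4 of 26 NF-κB and inflammation genes, namely Myd88, Nfkbia, Relb and Rela. Against marked genes only, the inflammation list was bound less often than other genes, at 3 of 17 (Fisher's exact test, adjusted p = 0.0470), where all protein-coding genes gave an adjusted p of 0.247 by Fisher's exact test. Retroelement silencing genes were bound at 9 of 18, led by Morc3 (15.3 and 34.5), nuclear receptors and coregulators at 10 of 25, and fibroblast and mesenchymal genes at 10 of 24, led by Postn (15.2 and 19.7) and Vim (12.6 and 22.2). Pluripotency genes were bound at 5 of 24, namely Klf2, Klf4, Klf5, Myc and Tbx3, endoderm genes at 4 of 15 and epithelial genes at 2 of 14. Of the markers of other cell types, 3 of 9 neural, 1 of 8 macrophage, 1 of 8 endothelial and 1 of 7 keratinocyte genes were bound, and 0 of 7 muscle genes, for which the exact interval reaches 41.0%. Fisher's exact test gave these 14 lists, exosome cofactors included, adjusted p-values between 0.149 and 1.

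**Figure D3:**
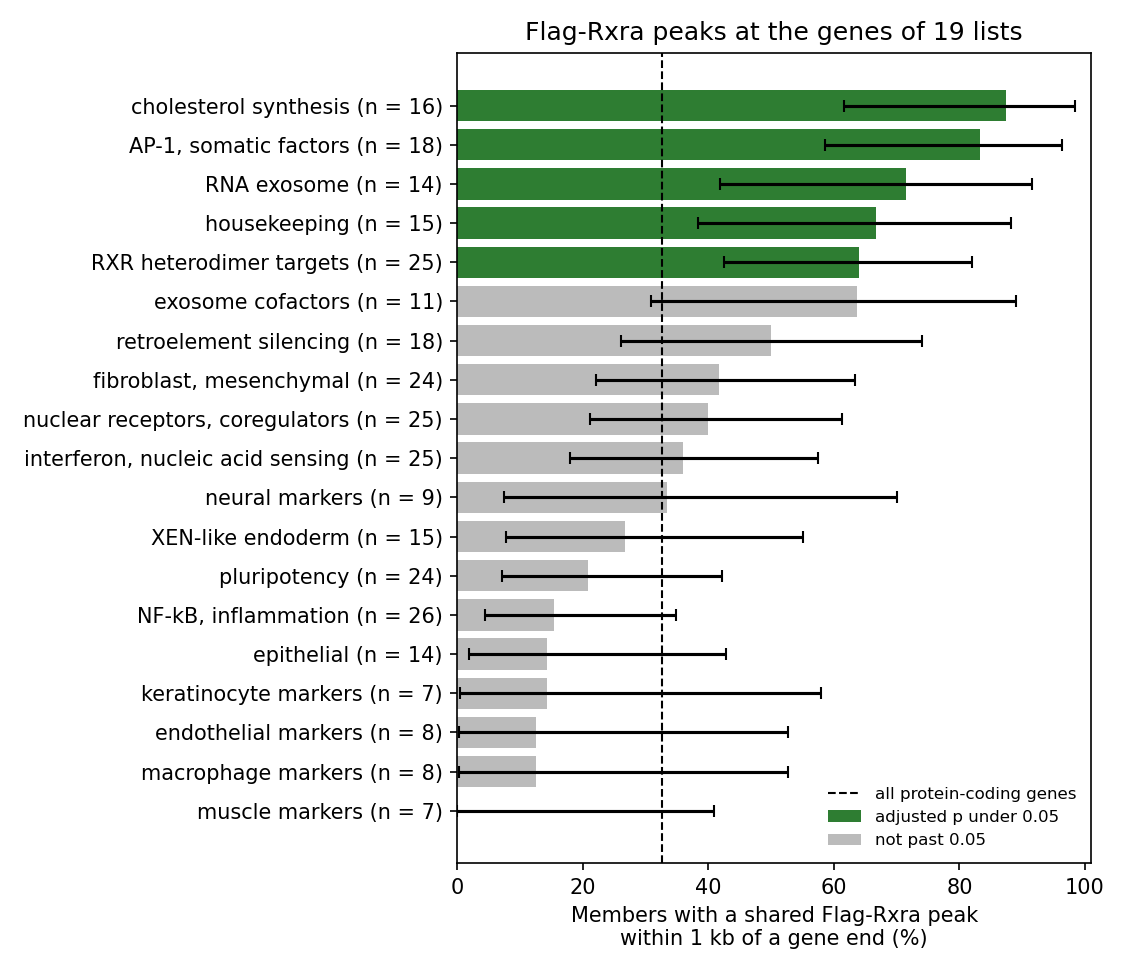
Percent of each list's members with a shared Flag-Rxra peak within 1 kb of a gene end (x axis), for 19 lists (y axis, with the number of members). Bars carry exact 95% binomial intervals, green bars passed an adjusted p of 0.05, and the dashed line marks the 32.6% of all protein-coding genes; 5 lists lie above it past the threshold.

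The second comparison set H3K27ac after CD against H3K27ac after DMSO. Most regions were called in 1 condition only. Of CD regions, 13.9% (13.7 to 14.2) overlapped a DMSO region, and 19.2% (18.9 to 19.5) of DMSO regions overlapped a CD region, against 2.37% and 3.26% by random placement. CD-only regions numbered 89879 and DMSO-only regions 60996. Shared regions were wider, at a median of 409 bp against 255 bp in CD and 453 bp against 293 bp in DMSO. They lay near gene ends more often, at 17.6% against 6.91% in CD and 17.8% against 8.64% in DMSO. Among the few regions with a −log10 q of 5 or more, 64.9% of 681 CD and 60.9% of 721 DMSO regions overlapped one another. Regions of 2 or more did so in 13.8% of CD and 14.4% of DMSO cases. Those of 5 or more lay near gene ends in only 4.70% of CD and 4.58% of DMSO cases. Weaker regions lay there in 8.42% and 10.4%, and random placement of the lists gave 3.63% and 3.70%. The higher overlap at 5 or more is therefore no evidence of common H3K27ac at genes. Because each condition had 1 list, the share of condition-only regions that 2 lists of a single condition would show is unknown.

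H3K27ac covered fewer bases after CD around interferon and nucleic acid sensing genes, counting called regions. Of the 25 genes, 17 had fewer covered bases in CD than in DMSO between 2.5 and 50 kb from their ends and 8 had more. The median difference of −559 bases lay at percentile 0.1 of matched random lists. Within 2.5 kb the median difference was −168 bases, at percentile 0.535. Within 50 kb, Irf9 had 3191 covered bases in CD and 5629 in DMSO, Stat2 3097 and 5101, and Bst2, an antiviral tether, 3209 and 5710, while Cxcl10 had 4031 in CD and 1766 in DMSO. Housekeeping genes stood apart in the same direction in the far window, with a median of −483 bases at percentile 1.1, and so did fibroblast and mesenchymal genes, with −159 bases at percentile 2.21. In the fibroblast list Twist2 had 6629 covered bases in CD and 9855 in DMSO, and Pdgfrb had 7102 and 3845. These were 4 of 38 medians outside the central 95% of random lists, where 1.9 are expected by chance. At a −log10 q of 5 or more, too few regions were left at these genes to compare the lists. With regions of 2 or more, both interferon medians lay inside. In the far window the median was −415 bases at percentile 2.91, with 16 genes lower in CD and 6 higher, and the mean difference lay at percentile 0.74. In the near window 4 genes were higher in CD, 3 were lower and 18 were equal, with the median at percentile 50 and the mean difference at 79.3. The fibroblast median also lay inside (53.9), as it did with 1 member per locus (2.60) and with bases weighted by fold (4.54). Housekeeping genes (2.21) and, in the opposite direction, endoderm genes (98.6) lay outside in the far window with regions of 2 or more.

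All 11 exosome cofactor genes had more covered bases in CD in the far window, with a median difference of 1509 bases at percentile 96.2 and a mean difference at percentile 99.6. With covered lengths matched between the lists, 9 of the 11 had more in CD, and the median of 1108 bases lay outside, at percentile 97.7. With regions of −log10 q of 2 or more, 6 had more in CD and 4 in DMSO, at percentile 70.2. Mtrex had 5248 bases within 50 kb in CD and 1000 in DMSO, and Zcchc7 had 3675 and 595. RNA exosome genes themselves had a median difference of 724 bases at percentile 65.4 in the far window and −294.5 bases at percentile 9.07 in the near window, and Exosc6 had 1659 bases in CD and 4688 in DMSO within 50 kb. Among macrophage markers the near window held a mean of 527 bases in CD and 56.2 in DMSO, at percentile 99.9 for the mean difference and 96.6 for the median, with Cd68 at 2184 and 0 bases. The medians of the other lists lay between percentiles 4 and 96.6 in the near window and between 8.78 and 96.2 in the far window. RXR heterodimer targets gave percentile 70.3 in the far window, with Abcg1 at 5974 bases in CD and 1477 in DMSO within 50 kb and Abca1 at 3210 and 6582.

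Over all protein-coding genes, 12920 had more covered bases within 50 kb in CD, 6900 had more in DMSO and 2067 were equal, with means of 3054 and 2616 bases. With covered lengths matched between the lists, 10078 had more in CD and 9356 in DMSO. Within 2.5 kb, 7833 had more in CD, 7032 had more in DMSO and 7022 were equal, with means of 319.9 and 320.1 bases. The 12 genes with the largest excess in CD stood at 7 loci, since 6 of them are predicted genes of 1 cluster on chromosome 6, where Gm40363 (47682344 to 47738326) had 22362 bases in CD and 12392 in DMSO. The others were Pdhx, a pyruvate dehydrogenase subunit (11286 and 3900), Gm2808, Acot11 (9848 and 2620), Sox13 (9934 and 2832), Rfx2 (10134 and 3081) and Ltbp1, a latent TGF-β binding protein (7844 and 840). The 12 genes with the largest excess in DMSO stood at 12 loci, led by Lhfp (chromosome 3, 53041547 to 53261679) with 1789 bases in CD and 10450 in DMSO. They also included Map4k4 (5818 and 12105), Nr1d2, a circadian nuclear receptor (1689 and 7456), Polr3f, an RNA polymerase III subunit (1388 and 7091), Rad51d (2160 and 7770) and Nedd4 (4245 and 9930). Flag-Rxra peaks lay at the ends of 4 of the 12 CD genes, Pdhx, Rfx2, Ltbp1 and Gm40364, and of 7 of the 12 DMSO genes. Of all protein-coding genes, 32.6% were bound. The CD genes stood at fewer loci than the DMSO genes, so the 2 counts are not a like comparison. None of the differences in covered bases has a replicate check. With regions of −log10 q of 2 or more, 22 of the 24 genes kept their sign, and at 5 or more too few regions were left to compare them.

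The last comparison set Flag-Rxra peaks beside H3K27ac. Shared Flag-Rxra peaks overlapped DMSO regions more often than CD regions, although the CD list was longer. Of the 17623 peaks, 6069 (34.4%, 33.7 to 35.1) lay in a DMSO region and 4736 (26.9%, 26.2 to 27.5) in a CD region, against 2.59% and 3.32% by random placement. Both lists held a region at 2715 peaks, CD alone at 2021, DMSO alone at 3354 and neither at 9533. Among genes, 64.1% of the 7128 bound genes were marked in DMSO and 60.9% in CD, whereas 22.2% of the other genes were marked in DMSO and 27.4% in CD. CD-only regions held a shared peak in 2.32% (2.22 to 2.42) of cases and DMSO-only regions in 5.24% (5.06 to 5.42), an odds ratio of 0.429 (two-sided Fisher's exact test, p = 4.08e-197, with regions not independent of each other). Within quartiles of region width the odds ratio ran from 0.411 to 0.593. Regions found in both conditions held a peak in 17.9% of CD and 19.2% of DMSO regions. With regions of −log10 q of 2 or more the odds ratio was 0.469 (p = 3.07e-55, Fisher's exact test). Among the 681 CD and 721 DMSO regions of 5 or more it was 1.29 (p = 0.362, Fisher's exact test), and the shares of peaks were 1.71% in CD and 1.68% in DMSO. These regions lay near gene ends in only 4.70% of CD and 4.58% of DMSO cases, against 3.63% and 3.70% by random placement. They therefore tell little about H3K27ac at genes. Replicate 2 alone gave shares of 15.6% in CD and 19.2% in DMSO.

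**Figure D4:**
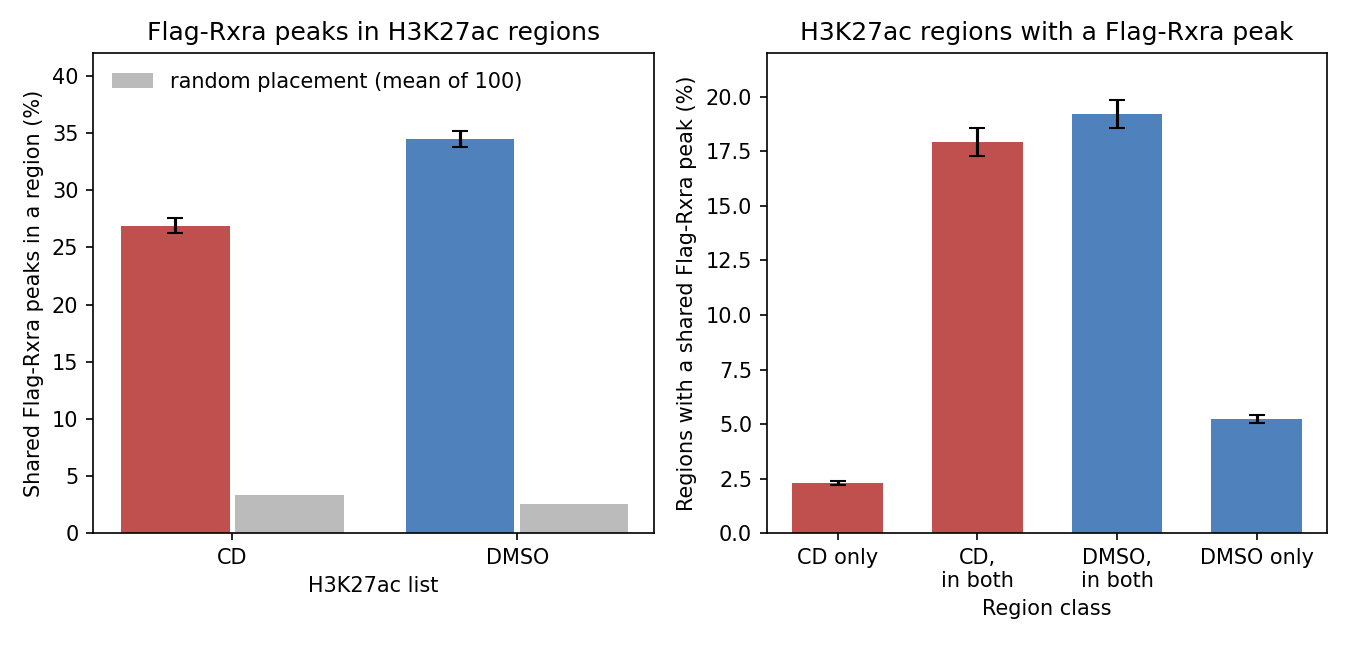
Left, percent of shared Flag-Rxra peaks that overlap an H3K27ac region (y axis) of each list (x axis), with random placement in grey; right, percent of H3K27ac regions that hold a shared Flag-Rxra peak (y axis) by region class (x axis). Error bars are exact 95% binomial intervals; the DMSO list holds 34.4% of peaks and the CD list 26.9%, and DMSO-only regions hold a peak in 5.24% of cases against 2.32% of CD-only regions.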

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

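Both tests on the strongest regions in this part were chosen after the data were seen. Peaks outside the analysed chromosomes are listed because no comparison of the report uses them and their number exceeds the 3 that a count of 0 allows, a low bar that says nothing about their origin. The DMSO list does not exceed it on the mitochondrial genome. The CD H3K27ac list held 6 regions on the mitochondrial genome and 120 on unplaced contigs, and the DMSO list 3 and 103. Flag-Rxra replicate 1 held 8 mitochondrial peaks and 34 on unplaced contigs, and replicate 2 held 13 and 45.

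The strongest regions were largely common to all 4 lists, whichever antibody was used. Of the 100 strongest regions of a list, 77 to 92 overlapped a region in each of the other 3 lists, and 45 or 46 overlapped regions among the 100 strongest of each. Of the 100 strongest shared Flag-Rxra peaks, 13% (7.11 to 21.2) overlapped the 1 kb window of a gene end, against 36.5% (35.8 to 37.2) of the other shared peaks. If these were sites where Rxra and H3K27ac meet at genes, strong peaks in both H3K27ac lists should lie near gene ends at least as often as other peaks in both lists, but they did so in 10.7% (5.02 to 19.4) against 53.6% (51.6 to 55.5). A candidate explanation is reads that pile up at the same places with any antibody, such as collapsed repeats, which stays open because no control library was used here. Leaving out the 263 shared peaks in H3K27ac regions of −log10 q of 5 or more in both lists changed the share of peaks in CD regions from 26.9% to 25.8%.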

How the results depend on the processing

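Settings at a −log10 q of 20 or 2, without the strongest common regions, with 1 member per locus and with peaks moved were chosen after the data were seen. No paired analysis was possible because each H3K27ac condition had 1 list for both replicates. The motif search and its alternatives were not run. The −log10 q of 5 removed no Flag-Rxra peak, so it says nothing about those lists. Depth is unknown. The cause was not tested for any change below unless the setting itself gives it.

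Overlap of Flag-Rxra replicate 1 and 2 peaks was 39.97% and 24.5% with 50% reciprocal overlap, 55.0% and 57.2% with lists of equal length, and 76.3% and 49.6% at −log10 q of 20. The share of shared peaks near gene ends was 42.8% with a 3 kb window, 33.1% with reciprocal overlap, 39.3% at −log10 q of 20 and 20.5% to 29.8% with 1 replicate left out. The share in CD and in DMSO regions was 1.71% and 1.68% with a −log10 q of 5, 6.87% and 10.5% with H3K27ac at 2, 30.6% and 39.9% with Flag-Rxra at 20, 17.7% and 24.5% for summits, and 25.8% and 33.4% without the strongest common regions. With 1 replicate left out it was 15.6% to 22.7% in CD and 19.2% to 28.0% in DMSO. CD exceeded DMSO only at a −log10 q of 5. Peaks moved by 50 to 500 kb instead of placed at random gave chance levels of 5.47% near gene ends, 5.38% in CD and 4.33% in DMSO regions. Overlap of CD with DMSO regions, and the reverse, was 5.37% and 7.44% with reciprocal overlap and 64.9% and 60.9% with −log10 q of 5. It was 15.7% and 17.5% with covered lengths matched and 13.8% and 14.4% with −log10 q of 2. The odds ratio of CD-only against DMSO-only regions was 1.29 with −log10 q of 5, 0.469 with H3K27ac at 2, 0.474 with covered lengths matched and 0.466 to 0.483 with 1 replicate left out.

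The number of gene lists past the threshold fell from 5 to 3 among marked genes, of which inflammation genes were bound less often and were not among the 5. It was 2 at −log10 q of 20 and 4 without the strongest common regions, where the housekeeping call was lost. Cholesterol synthesis and AP-1 genes stayed past it under all 8 alternatives, of which −log10 q of 5 and 1 member per locus changed nothing for them. The difference from other genes changed sign for neural markers, from 0.766 percentage points to −4.66 with a 3 kb window, −13.1 at −log10 q of 20 and −8.76 to −8.33 with 1 replicate left out. It did so for keratinocyte markers (−27.4 to 0.764, from −18.3) and interferon genes (−5.67 to 9.92, from 3.44) with 1 replicate left out, and among marked genes for interferon genes (−6.20) and nuclear receptors (−5.64). Of these lists, only nuclear receptors passed the threshold in any setting, without replicate 1. Medians of H3K27ac standing apart numbered 0 with −log10 q of 5, against 4, but so few regions were left that every median was 0, which says nothing about them. With 2 they numbered 2, of which only housekeeping genes were among the 4 and endoderm genes were new. Matched lengths added exosome cofactors, and 1 member per locus added epithelial genes and lost fibroblast genes. With bases weighted by fold (mean fold 3.25 in CD and 3.19 in DMSO) the fibroblast median turned positive, at percentile 4.54. In all, 170 of 240 alternative values stayed on their side of a threshold, within their 95% interval or, for counts, within 1.5 times the count. Of the values for the main comparisons, only 17 stayed, 36 moved out of these bounds and 1 reversed. The other 153 that stayed were of single gene lists or of counts of named genes. Some values could not change, since a −log10 q of 5 removed no Flag-Rxra peak.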

Other observations

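In this part, the test of enrichment at bound and unbound gene ends was chosen before its result was seen, the tests among genes with an H3K27ac region were planned as an alternative but set against an explanation only after their results were seen, and the tests of symbol groups, of regions of fixed width and against housekeeping genes were chosen after the result was seen. Other gene groups also differed in Flag-Rxra binding. Groups of at least 15 protein-coding genes that share the letters at the start of their symbol, which are not all true families, were compared with all other genes, and 37 of 157 were bound more often and 43 less often (Fisher's exact test, adjusted p under 0.05). The groups named here were chosen after their values were seen. Among those bound more often, peaks lay at 27 of 38 centrosomal Cep genes, 35 of 56 translation initiation Eif genes, 20 of 28 RNA polymerase Polr genes and 12 of 15 Timm genes of mitochondrial import (adjusted p = 3.21e-05, 7.09e-05, 0.00044 and 0.00129 by Fisher's exact test). Olfactory receptors (Olfr, 2 of 1110) and vomeronasal receptors (Vmn, 2 of 355) were bound less often (adjusted p = 2.92e-189 and 1.13e-55 by Fisher's exact test).

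Flag-Rxra peaks lay at 124 of 408 tRNA genes (30.4%, 26.0 to 35.1), close to the 32.6% of protein-coding genes. The shares were lower for snoRNA genes, at 51 of 1340 (3.81%), and for pseudogenes, at 129 of 9944 (1.30%). Away from the ends of protein-coding genes, 90 of 359 tRNA genes were bound (25.1%, 20.7 to 29.9) and 28 of 1258 snoRNA genes (2.23%). Per Mb, chromosome X held 0.133 to 0.254 times as many regions as the autosomes over the 4 lists, and 129 of 966 X-linked protein-coding genes were bound (13.4%) against 6998 of 20665 autosomal ones (33.9%). A gene had a median of 1 shared peak within 50 kb of its ends. The highest numbers were at Capzb and Smg6, with 17 each, and 14 lay around Ifnz, an interferon zeta gene in a cluster of similar genes on chromosome 4.

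Flag-Rxra peaks overlapped H3K27ac regions less often in the CD list than in the DMSO list, with a ratio of shares of 0.780 (95% bootstrap interval 0.759 to 0.802). The bootstrap resampled peaks, or genes for the factors below, so its intervals do not measure variation between cultures or libraries. Narrower CD regions do not account for all of the lower share, since regions set to 200 bp either side of their centres gave a ratio of 0.821 (0.797 to 0.845). The prediction for a uniformly lower enrichment of the CD list was an equal CD to DMSO factor of the excess over moved positions everywhere. The factor was 0.796 (0.767 to 0.825) at bound gene ends and 1.05 (0.893 to 1.21) at unbound ones, and the ratio of these factors was 1.32 (1.12 to 1.54). This cannot exclude lower enrichment, because called regions need not scale by 1 factor when signal falls. Unbound ends also exceeded moved positions little (15.9% against 12.5% in CD, 12.6% against 9.40% in DMSO). One hypothesis for the lower share and the lower factor at bound ends is that H3K27ac at Rxra-bound sites may be lower after CD. Differences between the libraries of the conditions, which 1 list per condition cannot separate from treatment, stay open. The treatment of the Flag-Rxra cells is not given, so a better match of their peaks to the DMSO list need not reflect an effect of CD at those sites. DMSO regions also lay near gene ends more often than CD regions (10.4% against 8.40%), and the ratio of shares was not adjusted for this. The odds ratio of CD-only against DMSO-only regions was 0.469 with regions of −log10 q of 2 or more, a setting chosen after the data were seen. It was 1.29 with the 681 CD and 721 DMSO regions of 5 or more, few of which lay near gene ends.

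Lists bound more often than other genes may reflect that Flag-Rxra peaks lie at the ends of active genes in general. Among genes with an H3K27ac region, AP-1 and cholesterol synthesis genes still passed (adjusted p = 0.0470 and 0.00467 by Fisher's exact test). Their shares were 86.7% and 100%, but marked housekeeping genes were also bound at 10 of 12 (83.3%). Passing this test therefore cannot separate the 2 lists from active genes in general. RNA exosome genes and RXR heterodimer targets did not pass (adjusted p = 0.251 and 0.331 by Fisher's exact test). Their shares of 76.9% and 68.4% stayed above the 50.6% of other marked genes, so the explanation could not be decided for them either. None of the 4 lists differed from housekeeping genes, bound at 10 of 15, by Fisher's exact test (adjusted p = 0.837 to 1), with few genes in each. H3K27ac regions called at a −log10 q of 1 are a loose measure of activity, and expression was not analysed here, so higher expression of these lists stays open.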
